A study of Mus musculus with 6 samples.

How the data were processed

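Total RNA of mouse kidneys at embryonic day 17 was prepared on columns with a DNase step, depleted of ribosomal RNA with a Ribominus kit and made into barcoded Ion Total RNA-seq libraries, per the labels' protocols. The genome build mm10 and the tool bedtools are named, without version or role, per the submitters' processing notes. The aligner, the gene annotation and any filter on reads are not given in the sources used here. The deposited signal is base coverage per gene: each value is the number of covered bases plus 1, multiplied by a factor per library that sets all 6 libraries to the same total. Covered bases here are summed depth, with a base counted each time it was covered, and not breadth of coverage. The histone gene Hist1h4a, which spans 23760692 to 23761230 on chromosome 13, had 150389 covered bases in control 5, far more than its length. This unit was read from the values. Each value divided by the smallest of its column was a whole number for 100% of values (tolerance 0.001), and the values above that floor summed to 1.05e+09 in every column. Covered bases are not reads and were not divided by gene length, so long transcripts weigh more, and the number of reads behind a value is unknown. The deposited group means are plain means of the columns. The deposited ratio is the mutant mean over the control mean, by the authors. The deposited p-value is unadjusted, and recomputation from the unlogged columns with equal variances gave the authors' values to within 9.36e-12.

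The design fixed before the data were examined foresaw counts or RPKM-like units. The table held neither, so the branch for normalized values was used and no count model was run. The factor was removed to recover covered bases (794 to 1235 megabases per library), which were scaled to a total of 1e+06 per library (BPM). A minimum of 1 and a pseudocount of 1 were set on the BPM scale rather than on the deposited scale, a choice made once the unit was known. On that scale 1 BPM is 794 to 1235 covered bases, depending on the library. Genes with at least 1 BPM in at least 3 libraries were kept (13977 of 23219). Fold changes are on the log2(BPM + 1) scale and understate the change of genes with low levels. Mutant was compared with control in limma 3.58.1 (R 4.3.3) with the trend and robust options and no covariate, two-sided, with Benjamini-Hochberg adjustment at 0.05. Groups came from the labels, and the label numbers are not shared between groups, so nothing pairs samples. Fold changes of a gene listed at 0 in all libraries of a group are not given.

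Gene lists (31, written before the data were examined) were tested with camera at a preset correlation of 0.01 and with the mean-variance trend of the same fit, for the 26 lists with at least 5 genes tested, with Benjamini-Hochberg adjustment over the 26. Camera was first run without the trend, which called 6 lists. The trend was then added because the design asks for the same fit, so that detail was settled after the result without it had been seen. The adrenal gland (3 genes tested), gonad (2), sex-linked (4), Six2 neighbour (4) and mitochondrially encoded (0) lists were too small to test. Principal components were computed on the centred log2 values of the genes tested. A score per kidney is the mean log2 level of a list's genes minus the mean of the control kidneys. Scores and single values were compared by exact permutation over the 6 kidneys, which cannot give a p below 0.1. Calls "adjusted over the list alone" use Benjamini-Hochberg over the members of that list.

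The genes named were set by a rule. They are Mta2, up to 12 genes past the threshold in each direction with no overlap between groups, or, where fewer pass, the genes with the smallest unadjusted p up to 8 in each direction, and up to 3 members of each list with the smallest p. Unnamed gene models were excluded from naming but stayed in all counts, and genes named outside the rule, apart from those that describe a library, are said to be. Some list members that the rule would name are not reported here. Coordinates are from GENCODE release M21 (mm10 coordinates, 1-based), in which 21587 of the 23219 symbols were found.

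The fit was tested on simulated data with the means and spread of these libraries and 13977 genes. Over 20 runs it recovered 29.2% of genes changed by 2-fold and 74.8% of genes changed by 4-fold, and 8.54% of its calls were unchanged genes, above the nominal 5%. Of the unchanged genes, 4.88% had an unadjusted p below 0.05. A list shifted by 0.4 was called in 20 of 20 runs, and 0.25 unshifted lists were called per run. The simulated genes were independent, so these list counts leave out correlation between genes.

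The alternatives covered quantile normalization, no filter and a minimum of 5 BPM, pseudocounts of 0.1 and 0.01, limma without trend, sample weights, other thresholds, erythroid genes left out of the totals, each library left out in turn, and for lists an estimated correlation, fry and no shared members. Median-of-ratios scaling, removal of abundant noncoding RNA genes and Lars2, and removal of both control 11 and mutant 6 were added after seeing the data, and the first camera run, without the trend, was kept as an alternative.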

Results

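RNA was measured in whole mouse kidneys at embryonic day 17, a stage at which new nephrons are still forming beside maturing tubules and glomeruli. The 6 libraries comprised 3 control kidneys with both Mta2 alleles floxed (numbered 5, 7 and 11 by the labels) and 3 mutant kidneys that also carried Six2 Cre (numbered 6, 8 and 9). Mta2 is a subunit of NuRD, the nucleosome remodelling and deacetylase complex. Six2 Cre acts in nephron progenitors, the cap mesenchyme cells that form the nephron epithelium from podocyte to distal tubule, while collecting duct, most stroma and endothelium come from other lineages. The comparison asks how gene expression in the embryonic kidney differs when Mta2 is deleted in this lineage, in a study that the title ties to focal segmental glomerulosclerosis (FSGS), a scarring disease of the glomerulus. Only mutant kidneys carried Cre, so Mta2 loss and the transgene cannot be told apart as the source of any difference.

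The libraries held 794 to 1235 megabases of summed coverage, with a base counted each time it was covered, over 23219 gene symbols. At least 1 covered base was present for 14467 to 16646 symbols. Read numbers are unknown, so no interval for counting error is given. The labels do not say that the kidneys came from separate embryos or litters, and the p-values measure only the spread between these samples, which may be technical. All 6 libraries came from male tissue, with the Y-linked gene Ddx3y at 51.1 to 144 BPM (covered bases in a library scaled to a total of 1e+06) and Xist, the transcript of the inactive X chromosome, at 0 to 0.0453. Control 11 stood apart, with 2.30% of its bases on Lars2 (0.0739% to 0.482% in the other libraries) and 1.17% on the noncoding RNA Rmrp. Mutant 6 also stood apart, at 70.3 on the first principal component (26.2% of the variance) against -26.2 to -4.38 in the other libraries. On the second component (21.1%) control 5 stood apart, at 55.0 against -39.3 to 9.03. Control 11 did so on the third (18.6%), at 54.5 against -28.6 to 8.05. Mutant 9 carried muscle transcripts, with titin (Ttn) at 173 BPM against 10.4 or less in the other libraries.

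Mta2 was lower in all 3 mutant kidneys than in all 3 control kidneys. Its level was 209 ± 11.0 BPM in control and 158 ± 26.6 BPM in mutant kidneys (SD, n = 3 each), so whole mutant kidneys held 75.5% of the control level, with cells outside the Six2 lineage included. The gene lies on chromosome 19 from 8941875 to 8952303 (plus strand, mm10). An exact two-sided permutation test gave p = 0.1, the smallest value that 3 against 3 samples allow. In limma the log2 fold change was -0.41 (SE 0.21, 95% interval -0.84 to 0.01), and the adjusted p was 0.887 (unadjusted 0.0572). Mta2 therefore did not pass the threshold, although the direction was that of the labels.

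**Figure D1:**
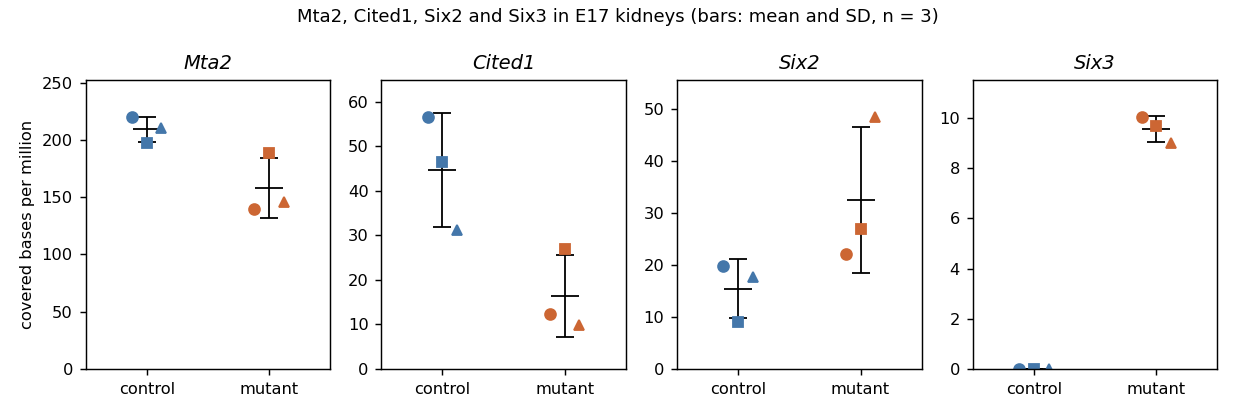
Level in BPM (y axis) of Mta2, Cited1, Six2 and Six3 in control and mutant E17 kidneys (x axis). Each point is a kidney, and bars give the mean and SD of 3. Mta2 lay at 198 to 220 BPM in control and 140 to 189 BPM in mutant kidneys, and Six3 was listed at 0 in all 3 control kidneys.

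Taken as lists, genes of the mature nephron tubule had lower levels in mutant kidneys, and genes of the kidney stroma and of dividing cells had higher levels. The proximal tubule list fell by a median of 0.41 on the log2 scale over 48 genes, the loop of Henle list by 0.36 over 20 and the distal tubule list by 0.41 over 17. The kidney stroma list rose by a median of 0.28 over 37 genes and the cell cycle list by 0.18 over 38. These were calls of camera with a preset correlation between genes of 0.01, and 8 of 26 lists passed an adjusted p of 0.05. With a correlation estimated from the 6 libraries 0 lists passed, and the smallest adjusted p was 0.151. The estimate was 0.30 for proximal tubule and 0.16 for distal tubule genes. It was 0.011 for stroma, -0.013 for loop of Henle and -0.011 for cell cycle genes, near or below the preset 0.01. For these last lists a larger correlation does not account for the lost calls. No single gene passed: limma called 0 of 13977 genes at an adjusted p of 0.05 and 0 at 0.1, and 783 genes had an unadjusted p below 0.05 (405 higher and 378 lower, against 699 by chance). Limma called 1 gene without its trend, 4 with sample weights, 8 without control 11 and 3 without mutant 8, and camera called 4 lists without control 7. Without both control 11 and mutant 6, a choice made after seeing the data, 22 genes and 13 lists passed. In all, 1567 genes (11.2%) had no overlap between the groups, against 10% by chance.

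The 8 genes with the smallest p among those lower in mutant kidneys included 4 markers from the tubule lists. Napsa, an aspartic protease of proximal tubule and lung (chromosome 7, 44572380 to 44586862), stood at 261 ± 53.5 BPM in control and 120 ± 17.6 BPM in mutant kidneys (SD, n = 3 each), a log2 fold change of -1.10 (SE 0.22). Lrp2, which encodes the endocytic receptor megalin (chromosome 2, 69424340 to 69586065), stood at 3992 ± 443 and 2360 ± 671 BPM (log2 fold change -0.79, SE 0.16). Umod, the uromodulin gene of the thick ascending limb (chromosome 7, 119462711 to 119479282), stood at 131 ± 29.6 and 56.5 ± 16.2 BPM (log2 fold change -1.21, SE 0.27). Slc12a3, the thiazide-sensitive sodium chloride cotransporter of the distal convoluted tubule (chromosome 8, 94329201 to 94366214), stood at 76.9 ± 11.3 and 32.8 ± 6.63 BPM (log2 fold change -1.22, SE 0.29). The other 4 were Snap91, a clathrin assembly protein (chromosome 9, 86765923 to 86880654, log2 fold change -1.57), Ndrg1 (chromosome 15, 66929318 to 66969640, -0.88), Acmsd, an enzyme of tryptophan breakdown (chromosome 1, 127729413 to 127767978, -1.71), and Klhdc8a (chromosome 1, 132298626 to 132307357, -2.88). All 8 were lower in every mutant kidney than in every control kidney, with limma adjusted p from 0.12 (Napsa, Lrp2, Snap91, Umod and Ndrg1) to 0.224 (Slc12a3). Choice by smallest p favours genes without overlap, so this separation adds no support.

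The 8 genes with the smallest p among those higher in mutant kidneys were Nxph1, Six3, Aldh1a3, Tbx3, Hist1h4a, Id3, Calb1 and Fat4. Aldh1a3, an enzyme that makes retinoic acid (chromosome 7, 66390890 to 66427517), stood at 66.3 ± 2.68 BPM in control and 139 ± 6.48 BPM in mutant kidneys (SD, n = 3 each), a log2 fold change of 1.06 (SE 0.24). Tbx3, a T-box transcription factor (chromosome 5, 119670669 to 119684724), stood at 107 ± 8.79 and 204 ± 6.55 BPM (log2 fold change 0.92, SE 0.22). Fat4, a large protocadherin of the renal stroma (chromosome 3, 38886940 to 39011985), stood at 589 ± 184 and 951 ± 132 BPM (log2 fold change 0.73, SE 0.19). Id3, an inhibitor of helix-loop-helix transcription factors (chromosome 4, 136143497 to 136145755), had a log2 fold change of 0.94, the calcium-binding protein gene Calb1 (chromosome 4, 15881264 to 15908064) 0.91 and the histone gene Hist1h4a (chromosome 13, 23760692 to 23761230) 0.85. Without control 11 the log2 fold change was 0.48 for Fat4 and 0.60 for Id3. Nxph1, which encodes a neurexin ligand (chromosome 6, 8948431 to 9249032), read 8.36, 7.11 and 23.6 BPM in mutants 6, 8 and 9 and was listed at 0 in controls 5 and 7 and at 0.172 in control 11. Six3, a homeobox gene close to Six2 (chromosome 17, 85613608 to 85629302), was listed at 0 in all 3 controls and read 10.03, 9.70 and 8.99 BPM in mutants 6, 8 and 9. The limma adjusted p ran from 0.12 (Nxph1, Six3 and Aldh1a3) to 0.336 (Calb1 and Fat4), and the 3 mutant values lay above the 3 control values for each of the 8, which the choice by smallest p also favours.

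**Figure D2:**
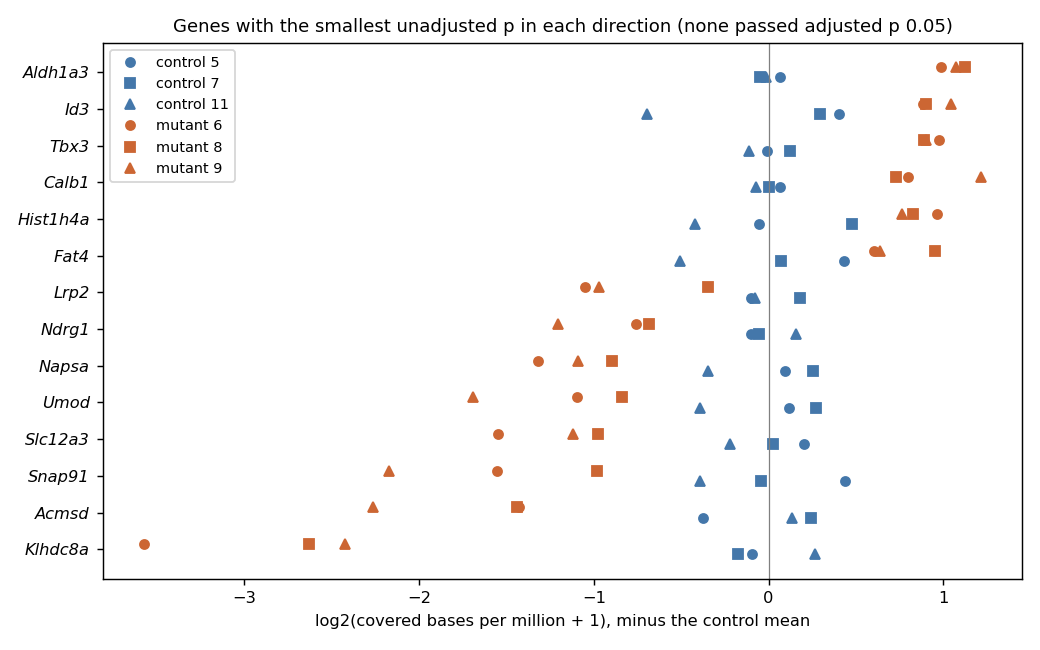
Level of 14 of the 16 genes with the smallest p in each direction in each E17 kidney, as log2(BPM + 1) minus the control mean (x axis), 1 line per gene. Six3 and Nxph1, listed at 0 in at least 2 control kidneys, are left out. Each mutant kidney lies beyond all 3 control kidneys for every gene shown, which choice by smallest p favours, and limma adjusted p was 0.12 or more.

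The proximal tubule takes up filtered protein, sugar and organic ions, and 45 of its 48 genes had a log2 fold change below 0. Slc22a6, the organic anion transporter of the basolateral membrane, stood at 245 ± 102 BPM in control and 115 ± 24.3 BPM in mutant kidneys (log2 fold change -1.02), and Cubn, which encodes cubilin, the partner of megalin, at 696 ± 139 and 438 ± 90.2 BPM (log2 fold change -0.67, SD, n = 3 each). Of the 48 genes 0 passed adjusted over all genes and 12 passed adjusted over the list alone, all of them lower. The camera test of the list gave adjusted p = 4.00e-19 with the preset correlation and adjusted p = 0.232 with an estimated correlation, which came to 0.30 between these genes. Kidneys varied along these genes within a genotype: the mean log2 level relative to control was -0.25 in control 5 and -0.23 in mutant 8, so the groups overlapped (exact p = 0.2). Grouping control 5 with mutants 6 and 9 gave a median of 0.48 in size, larger than the 0.41 of the genotypes.

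Loop of Henle and distal tubule genes, which serve salt and divalent ion transport, had lower mean levels as lists in every mutant kidney, but not all members fell. Slc12a1, a loop of Henle member named outside the rule, overlapped between the groups. It had 344974, 292650 and 341302 covered bases in controls 5, 7 and 11 and 437780, 328137 and 290810 in mutants 6, 8 and 9, not scaled to library totals. Tmem72 stood at 51.4 ± 14.0 BPM in control and 19.98 ± 12.6 BPM in mutant kidneys (log2 fold change -1.44, SD, n = 3 each). In the loop of Henle list 14 of 20 genes lay below 0, 0 passed adjusted over all genes and 3 adjusted over the list alone (Umod and Tmem72 among them). Its camera adjusted p was 5.49e-04, and adjusted p = 0.151 with an estimated correlation. In the distal tubule list 13 of 17 genes lay below 0, 0 passed adjusted over all genes and 3 adjusted over the list alone, of which Slc12a3 and Tmem52b (log2 fold change -0.68) were lower and Calb1, a gene that the ureteric bud also expresses, was higher. Its camera adjusted p was 9.04e-04, and adjusted p = 0.338 with an estimated correlation, and without control 7 it was 0.0635. The distal tubule median was -0.25 without control 7 and -0.26 without mutant 9. For both lists every mutant kidney scored below every control kidney (exact p = 0.1, the smallest possible).

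Stromal genes as a list were higher in every mutant kidney, at a mean log2 level of 0.25 to 0.30 against -0.08 to 0.14 in control kidneys (exact p = 0.1, n = 3 each). Of 37 genes 29 lay above 0 and 8 below, and 8 were higher and 1 lower with no overlap between the groups. The rise was therefore not shared by all stromal genes. Of the list 0 passed adjusted over all genes, and 2 passed adjusted over the list alone, Fat4 and Cldn11, a tight junction gene (28.5 ± 4.14 BPM in control and 57.9 ± 7.32 BPM in mutant kidneys, log2 fold change 1.00). Pdgfra, a receptor of interstitial fibroblasts, stood at 275 ± 71.5 and 408 ± 44.2 BPM (log2 fold change 0.60). The camera adjusted p of the list was 1.33e-04, and adjusted p = 0.151 with an estimated correlation. The fibrosis and matrix remodelling list was not called (median 0.06, camera adjusted p = 0.239), with Vcan at 0.93, Mmp9 at 1.38 and Postn at 0.62 on the log2 scale. Without control 11 Fat4 was at 0.48, Pdgfra at 0.38, Vcan at 0.57 and Postn at 0.21.

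Cell cycle genes as a list were higher in every mutant kidney, by 0.21 in each of the 3 in mean log2 level (exact p = 0.1, n = 3 each). The list rose with 29 of 38 genes above 0, among them Ccne2 (log2 fold change 0.85), Cdk1 (0.44) and Ube2c (0.51), drivers of the G1/S step, of mitosis and of its exit, with 0 genes past adjusted over all genes and 0 adjusted over the list alone. Other genes of the G1/S step and of replication moved both ways (named outside the rule). Ccne1 was at -0.29, Mcm5 at -0.18, Mcm3 at -0.12, Mcm7 at -0.10 and Mcm2 at -0.07, against Mcm4 and Mcm6 at 0.15 and Pcna at 0.18. Camera gave the cell cycle list adjusted p = 4.42e-03, and adjusted p = 0.151 with an estimated correlation, and the median was 0.28 without mutant 9 and 0.09 without both control 11 and mutant 6. The replication-dependent histone list, whose genes are transcribed during DNA synthesis, rose by a median of 0.13 with 19 of 30 genes above 0. Hist1h4a alone passed adjusted over the list alone, 0 passed adjusted over all genes, and Hist1h1c and Hist1h4b had log2 fold changes of 0.62 (0.40 without control 11) and 0.61. Camera gave the histone list adjusted p = 0.0201, adjusted p = 0.232 with an estimated correlation and adjusted p = 0.113 without the mean-variance trend. The histone call was also lost without control 5 (adjusted p = 0.268), control 7 (0.0622), mutant 6 (0.0543) or mutant 8 (0.0676), and the median was 0.06 without control 5 and 0.20 without control 11.

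Podocyte genes, which build the glomerular filter, fell by a median of 0.14 over 49 genes, of which 32 lay below 0. Col4a3, a collagen of the glomerular basement membrane, stood at 53.2 ± 19.4 BPM in control and 30.2 ± 6.19 BPM in mutant kidneys (log2 fold change -0.76, or -0.48 without control 5), and Enpep, an aminopeptidase that cleaves angiotensin, at 657 ± 101 and 476 ± 52.8 BPM (-0.46, SD, n = 3 each). None of the 49 passed, 0 adjusted over all genes and 0 adjusted over the list alone. The camera adjusted p was 0.0128, and adjusted p = 0.347 with an estimated correlation, 0.0639 without control 5, 0.0741 without control 7 and 0.0964 without mutant 6. The podocyte median was -0.21 without control 5, -0.23 without control 7, -0.09 with a minimum of 5 BPM and -0.07 with members shared between lists left out. Control 11 (-0.105) scored below mutant 8 (-0.0904), so the groups overlapped (exact p = 0.2). The renin-angiotensin list fell by a median of 0.22 over 10 genes, with Ace (log2 fold change -0.56), Enpep (-0.46) and Ren1 (-0.55, but -0.91 without control 7, -0.23 without control 11 and -0.26 without mutant 6), and 0 past adjusted over all genes and 0 adjusted over the list alone. Camera gave adjusted p = 0.0198, adjusted p = 0.338 with an estimated correlation and 0.104 without the mean-variance trend, and the call was lost without control 7 (0.139) or mutant 8 (0.0676). Its median was -0.13 without control 7, -0.37 without control 11 and -0.46 without both control 11 and mutant 6.

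The list of genes mutated in inherited FSGS and nephrotic syndrome did not pass (58 genes, median -0.07, camera adjusted p = 0.0682), with 35 below 0 and Cubn and Col4a3 first by p. Fry tests a list by itself, whereas camera sets it against the other genes. For the FSGS list fry gave adjusted p = 0.425 for a shift in 1 direction and 0.0159 for change in either direction. The fry test of either direction passed 6 lists, and gave 0.244 for podocyte, 0.0904 for proximal tubule and 0.47 for basement membrane genes. The basement membrane list did not pass camera either (26 genes, median -0.09, adjusted p = 0.0682). Its first members by p were Col4a3, Lama2 (log2 fold change 0.44) and Col4a2 (-0.27). In both lists 0 genes passed adjusted over all genes and 0 adjusted over the list alone.

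Nephron progenitor genes moved apart and the list was not called (27 genes, median 0.04, mean -0.01, camera adjusted p = 0.833). Cited1, a marker of the least committed cap cells (chromosome X, 102247381 to 102252181), stood at 44.7 ± 12.8 BPM in control and 16.4 ± 9.18 BPM in mutant kidneys (log2 fold change -1.48, SE 0.39), and Meox1 at 27.5 ± 5.39 and 11.5 ± 4.11 BPM (-1.24). Eya1, a partner of Six2 (chromosome 1, 14168954 to 14310235), stood at 45.7 ± 6.36 and 87.0 ± 19.7 BPM (log2 fold change 0.90, SE 0.27). Six2, the progenitor factor whose name the Cre carries (chromosome 17, 85684277 to 85688274, named outside the rule), stood at 15.4 ± 5.74 BPM in control and 32.4 ± 14.0 BPM in mutant kidneys (log2 fold change 1.01, SE 0.42). Only mutant kidneys carried the Cre transgene, so its own contribution to Six2 reads was not separated from that of the progenitors. All 4 were separated by genotype, which choice by smallest p favours for Cited1, Meox1 and Eya1, so the separation of those genes adds no support. Of the list 0 passed adjusted over all genes and 2 adjusted over the list alone (Cited1 lower, Eya1 higher). Fry gave the list adjusted p = 0.0389 for change in either direction and 0.61 for a shift in 1 direction.

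Neighbouring compartments and signals were not called by camera. Early nephron genes had a median of -0.17 (adjusted p = 0.113), with Wnt4 at 0.41 and Lef1 at 0.86 on the log2 scale. Ureteric bud tip genes had a median of 0.33 (adjusted p = 0.089), with Wnt11 at 0.72 and Gfra1 at 0.50, and scored higher in every mutant kidney (exact p = 0.1, n = 3 each). Wnt target genes also scored higher in every mutant kidney (median 0.35, exact p = 0.1), with 13 of 20 genes above 0, among them Axin2 at 0.84 and Apcdd1 at 0.53, and 7 below 0, among them Cited1 at -1.48. In that list 3 genes were higher and 3 lower with no overlap between the groups. Camera gave the Wnt list adjusted p = 0.154 and fry 0.0113, and Cited1 alone passed adjusted over the list alone. The Notch pathway list had a median of -0.11 (adjusted p = 0.116), with 10 genes below 0 and 9 above. Lfng was at -0.73, Notch4 at -0.72 and Nrarp at -0.66. Over the alternative settings Notch4 ran from -0.99 to -0.31 and Nrarp from -1.02 to -0.24. Collecting duct genes had a median of 0.01 (adjusted p = 0.861), with Calb1 the only gene past adjusted over the list alone, Scnn1a at -0.70 (-1.05 to -0.32 over the alternative settings) and Hsd11b2 at 0.80 (0.67 to 1.03). The NuRD list, Mta2 included, had no call (14 genes, median 0.19, adjusted p = 0.239), with Mta3 at 0.52 (0.31 to 0.66 over the alternative settings) and Chd3 at 0.28 (0.16 to 0.36). In these lists 0 genes passed adjusted over all genes, and apart from Cited1 and Calb1 0 passed adjusted over the list alone.

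Markers of other cell types and of tissue state were not called by camera. Endothelial genes had a median of -0.05 (adjusted p = 0.517) and a slightly lower score in every mutant kidney (-0.05 to -0.04 against -0.03 to 0.02), with Sox17 at 0.77, Robo4 at -0.73 and Egfl7 at 0.40. Macrophage and leukocyte genes had a median of -0.22 and a mean of -0.03 (adjusted p = 0.861), with Mrc1 at 0.94, Ptprc at 0.82 and Tyrobp at -1.36. Tyrobp had low mean levels, at 4.89 BPM in control and 1.03 BPM in mutant kidneys. The erythroid list (median 0.04, adjusted p = 0.935) had Hba-a1 at 0.36. The p53 target list (median 0.05, adjusted p = 0.833) had Polk at 0.99, Zmat3 at 0.66 and Mdm2 at 0.48. Kidney injury genes had a median of 0.15 (adjusted p = 0.367 in camera and 0.00258 in fry) and scored higher in every mutant kidney, with Fga at 1.55, Krt20 at 1.47 and Timp1 at -1.06. Only 12 of the 20 listed genes were tested. Mean levels in control and mutant kidneys were low, at 0.995 and 4.33 BPM for Fga, 1.40 and 4.94 for Krt20, and 5.69 and 3.03 for Timp1. Havcr1 and Lcn2 (named outside the rule) were not tested. Havcr1 had 0, 0 and 1574 bases in controls 5, 7 and 11 and 0 in all 3 mutants. Lcn2 had 0, 572 and 476 in controls 5, 7 and 11 and 0, 2213 and 0 in mutants 6, 8 and 9. The list of immediate early and heat shock genes had a median of -0.02, a mean of 0.04 and adjusted p = 0.833, with Egr1 at 1.30, Klf2 at 1.01 and Zfp36 at -0.96. The neuron and nerve list had a median of -0.03, a mean of 0.06 and adjusted p = 0.981, with Nefl at 1.37, Fabp7 at -1.15 and Elavl4 at -0.78. These genes had low mean levels in control and mutant kidneys, at 1.17 and 5.12 BPM for Nefl, 2.57 and 0.53 for Fabp7, and 6.48 and 3.65 for Elavl4. Skeletal muscle genes (median 0.74, adjusted p = 0.0682), including Neb at 1.99, Mylpf at 1.85 and Myh3 at 2.10, were high mainly in mutant 9, whose mean log2 level was 2.48 against 0.42 in mutant 8 and -0.33 in mutant 6. In all of these lists 0 genes passed adjusted over all genes and 0 adjusted over the list alone.

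**Figure D3:**
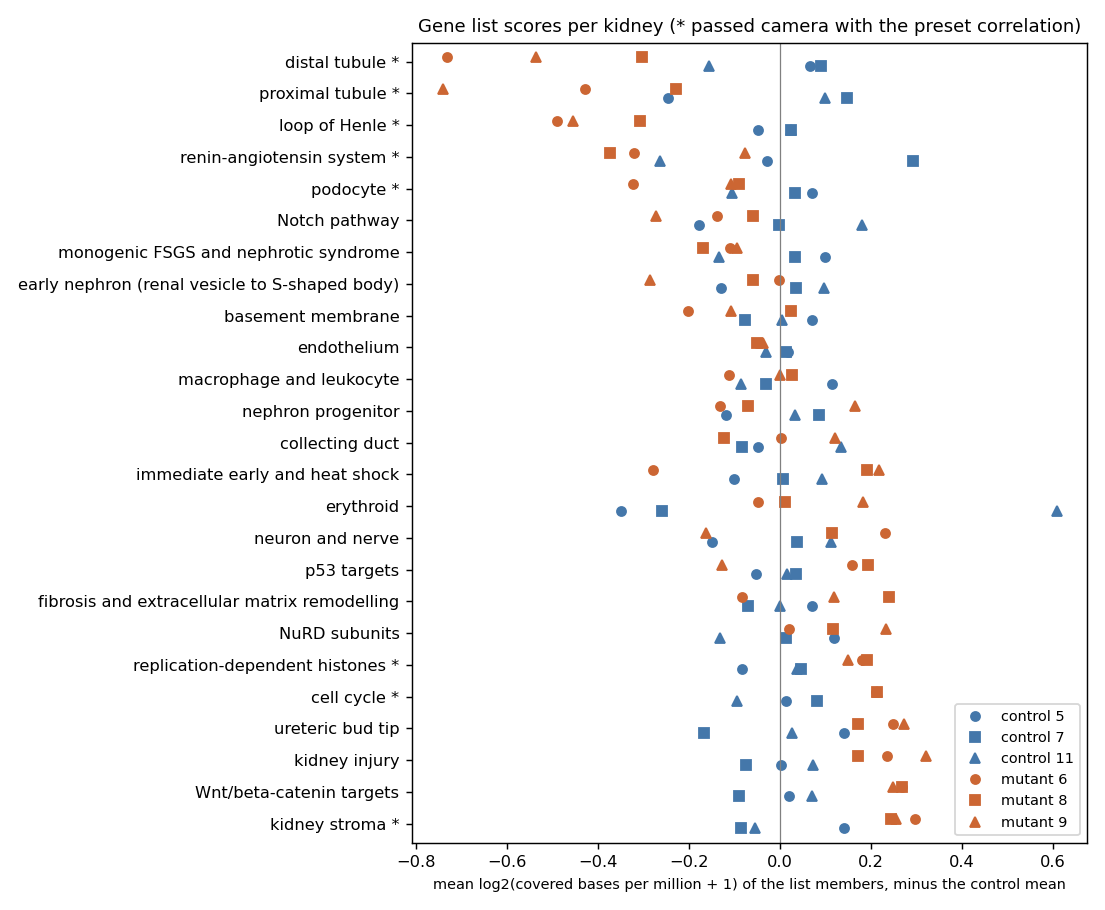
Mean log2(BPM + 1) of the members of each gene list, minus the control mean (x axis), in each of the 6 kidneys, 1 line per list; skeletal muscle, which runs off this scale in mutant 9, is left out. Stars mark the 8 lists that camera called with the preset correlation, none of which passed with an estimated correlation. Loop of Henle and distal tubule scores lie lower, and stroma and cell cycle scores higher, in all 3 mutant kidneys, while the proximal tubule scores of control 5 (-0.25) and mutant 8 (-0.23) lie side by side.

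The authors' deposited table gives an unadjusted p for each gene, below 0.05 for 760 of 23219 genes (3.27%) and for 725 of the 13977 genes tested here. Mta2 had a ratio of means of 0.755 and an unadjusted p of 0.0369 in the authors' deposited table. After Benjamini-Hochberg adjustment of the authors' deposited p-values 0 genes passed 0.05, and the smallest adjusted p was 0.144.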

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

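Median-of-ratios scaling, removal of abundant noncoding RNA and removal of both control 11 and mutant 6 were chosen after seeing the data. Camera without the mean-variance trend was the first run, and the trend was settled on after its result had been seen. The others were set before the data were examined. Mta2 stayed lower and short of the threshold in all 17 settings (log2 fold change -0.55 to -0.33). The limma count of 0 genes became 1 with quantile normalization (Napsa), 1 without the trend (Six3), 4 with sample weights (Napsa, Nxph1, Snap91 and Umod), 2 without abundant noncoding RNA (Napsa and Lrp2), 22 without control 11 and mutant 6, and 0 to 8 with 1 library left out, 8 without control 11 and 3 without mutant 8 (Lrp2, Snap91 and Kap, a kidney androgen-regulated gene named after its values were seen). The count of 8 lists became 0 with an estimated correlation, 3 with fry (loop of Henle at 0.033, and Wnt targets and kidney injury, which are not among the 8), 13 without control 11 and mutant 6, and 4 to 12 with 1 library left out, 4 without control 7. With an estimated correlation adjusted p was 0.151 for the kidney stroma, loop of Henle and cell cycle lists, 0.232 for proximal tubule and histones, 0.338 for distal tubule and renin-angiotensin and 0.347 for podocyte. Fry gave 0.0535 for stroma and cell cycle, 0.139 for histones, 0.169 for distal tubule, 0.192 for proximal tubule, 0.376 for podocyte and 0.413 for renin-angiotensin. With shared members left out podocyte had 0.191 and renin-angiotensin 0.16. Renin-angiotensin had 0.0626 without a filter and 0.104 without the trend, where histones had 0.113. With 1 library left out adjusted p ran from 8.78e-05 to 0.0635 for distal tubule, 2.51e-04 to 0.0964 for podocyte, 6.13e-05 to 0.139 for renin-angiotensin and 7.38e-05 to 0.268 for histones, and the proximal tubule, stroma, loop of Henle and cell cycle lists passed in each. Over all settings adjusted p ran from 5.72e-25 to 0.232 for proximal tubule, 7.32e-07 to 0.151 for stroma, 3.61e-04 to 0.151 for loop of Henle and 2.75e-03 to 0.151 for cell cycle. List medians ran from -0.54 to -0.25 for distal tubule, -0.23 to -0.07 for podocyte, -0.46 to -0.13 for renin-angiotensin, 0.06 to 0.20 for histones and 0.09 to 0.28 for cell cycle. The 8 lists kept their direction in every setting. Of 81 genes set by the naming rule, Mta2 aside, 32 had a log2 fold change that moved by over 1.5 times when 1 library was left out, 14 of them without control 11. Among the named genes Egfl7 (-0.0504) and Ren1 (0.067) reversed without control 11 and mutant 6. The cause was not tested for any of these changes. Median-of-ratios scaling, no filter, a minimum of 5 BPM, the other pseudocounts and erythroid genes left out gave 0 genes. Not run were the count-only alternatives (the table holds no counts), a sex covariate (all 6 male), merging of duplicate symbols (none occur) and the mitochondrial part of the erythroid alternative (no such symbols in the table). Read depth is unknown, so no counting error is given for any value.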

Other observations

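The test on Six3 and Six2 reads, the dilution and age comparisons, and the use of the proximal tubule median with each library left out as a test of a single-library cause were chosen after the list results or gene values had been seen; leaving out each library was itself planned. The tests of Six3os1, of bias correction, of the splits and of the Slc family were written down before their values were computed, but after the list results were known.

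Ribosomal protein genes had a median above 0 that rested largely on control 11, in a scan of 75 symbol families made after the lists had been tested. The 77 genes for cytosolic ribosomal proteins had a median log2 fold change of 0.32, with 59 higher, 0 past adjusted over all genes and 0 adjusted over these genes alone. This set was chosen after the scan of the same data, so its p-values, unadjusted for the scan, are no independent support. Camera gave p = 1.03e-06 with the preset correlation and p = 0.244 with an estimated correlation. The median was 0.09 without control 11, whose score of -0.45 was the lowest of the 6, and the exact p over kidneys was 0.4 (n = 3 each). In the same scan the Rps and Rpl families passed (adjusted p = 4.74e-04 and 1.28e-03, and 0.885 for both with an estimated correlation) and solute carriers did not (295 Slc genes, median -0.10, adjusted p = 0.129). The families were symbol prefixes, and Rps also held genes outside the 77, such as Rps6ka2 (log2 fold change -0.51) and Rps19bp1 (0.91). Without members of the fixed lists the 270 other Slc genes had adjusted p = 0.381, so whether transporters outside the tubule lists shifted stays open.

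Tubule lists were lower and the stroma list higher in mutant kidneys, and for the proximal tubule list no single library made this: with each library left out the median stayed between -0.58 and -0.30, nearest 0 without mutant 9, while the distal tubule call was lost without control 7 (adjusted p = 0.0635). Correction of each library for trends with GC content, transcript length and mean level left the proximal tubule median at -0.46, with values for 100% of list members, though it also took the called lists from 8 to 10, adding basement membrane (adjusted p = 0.0233) and ureteric bud tip (0.0377), and moved the renin-angiotensin median from -0.22 to -0.36. A loss of tubule cells that raised the share of all other cell types alike was weighed only after the list medians were known. The stroma median lay 0.33 above the endothelium median (permutation p = 0.00253 over genes, which are not independent). The stroma minus endothelium score of all 3 mutant kidneys lay above that of all 3 controls. Because the lists were chosen with their medians known, this is no independent test. It shows that stroma and endothelium lists did not rise alike, and does not decide on such a loss. A candidate explanation that stays open is a difference in age at collection: the collecting duct median was 0.0126, with members on both sides of 0, and mutant and control embryos cannot be told apart by age from these data, nor was delayed or reduced tubule formation after Mta2 loss tested. An effect of the Cre transgene itself, carried only by mutants, also stays open. The 3 against 3 design gives 10 splits, too few for a share under 0.05: the genotype split called 8 lists and the highest other 3, the gene count says nothing here because the genotype split called 0 genes, which all 10 splits must reach (highest other 1), and in 2 of 10 the proximal tubule median was as large.

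Six3 was listed at 0 in the 3 control libraries and had 10876, 9105 and 8943 covered bases in mutants 6, 8 and 9, the only gene at 1 BPM or more in all 3 mutants and at 0 in all 3 controls, while 4 genes had the opposite pattern (2610035D17Rik, Gbp3, Mcoln2 and Kiss1r, named after their values were seen). The Six3 to Six2 ratio of covered bases was 0.186 or more in mutants and 0 in controls, which had 11034 to 21713 Six2 bases. Six2 reads of the kind that controls hold were therefore not assigned to Six3 at such a ratio. With Six3 at 0 in controls any mutant value would have passed this comparison. It cannot speak to reads from a transgene that only mutants carry. A candidate source is the Cre transgene, because Six2 Cre drivers can be built from a large genomic fragment around Six2, and the labels do not name the driver; Six3os1, beside Six3, had bases in 0 mutant libraries, which was to count against extra copies. That reading was dropped after the value was seen, since Six3os1 was at 0 in every library, including mutants in which Six3 was read, and so cannot report copies. As only mutants carried Cre, the transgene and the loss of Mta2 cannot be told apart as the source of Six3. The same limit holds for the higher Six2 values and for every other gene or list that differed between the groups.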
